A study of Drosophila melanogaster with 185 samples.

How the data were processed

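RNA was measured in 101 libraries of Drosophila melanogaster, given as 185 samples because 84 libraries were sequenced in 2 runs. They comprised 72 libraries of neurons in 14 groups, 27 of whole flies in 8 genotypes and 2 of brains. Neurons were harvested by patch pipette and their RNA was amplified by a SMARTer protocol, per the labels' protocols. The authors deposited read counts per gene for every sample, with no normalization. Reads were trimmed with cutadapt, aligned with TopHat2, Bowtie and Bowtie2 to BDGP5 and counted with HTSeq, and the study's own tests used DESeq2, per the submitters' processing notes. A compiled table of counts and a corrected table in CPM were also deposited, and neither entered a comparison. Gene symbols are those of the deposited counts, an older annotation in which the dopamine receptor genes are DopR and DopR2. No coordinates are given, because the reference at hand is of another build. The counting rule for reads shared by near-identical copies, such as the Hsp70, yolk protein and ribosomal protein genes, is not stated, so single members of those families are uncertain.

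The runs of a library were summed. In 81 of the 84 libraries with 2 runs, the runs agreed within sampling noise (chi-square per degree of freedom 0.976 to 1.044, over genes with at least 20 reads). One of the other 3 is an alpha/beta control library deposited as a pair of samples, which was summed. The pair differed by a chi-square per degree of freedom of 35.3, where the lowest between separate alpha/beta control libraries was 30.44, so it may be 2 libraries, and it was also counted as 2 replicates. The remaining 2 are 3-86 trained library 2 and 3-86 control library 3: run 2 of the trained library matched run 1 of the control library (r = 0.9985, chi-square per degree of freedom 1.065), so each sum holds RNA of different origin under its label. They were kept as labelled, and comparisons were repeated without both. No pair of libraries within a group matched this closely, with the lowest chi-square per degree of freedom at 12.36. In the compiled table, 88 of 101 columns equalled the sum of a library's runs, 2 held a single file, 7 held another library's counts and 4 matched no library. That table also turned 5 gene symbols into numbers and lacked 1 library.

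Groups followed the labels: 7 neuron classes, each control and trained, and 8 whole-fly genotypes. Replicates are libraries, and the p-values measure the spread between libraries. The deposited counts hold 15682 genes. Genes passing edgeR's filterByExpr were tested in edgeR 4.0.16 under R 4.3.3, with TMM scaling, a robust quasi-likelihood fit and 2-sided tests. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Training was fitted within each class. The class comparisons shared a fit of the 7 control groups, and each class was set against the average of the other class means on the log scale. That fit gave each gene 1 spread for all classes, with a common coefficient of variation of 1.274 between libraries. Training fits within a class gave 0.435 in gamma, 0.7162 in alpha/beta, 0.9575 in V2, 1.188 in V3, 1.21 in DAL, 1.435 in R27G01 and 1.526 in 3-86. Class p-values may therefore be too small for 3-86 and R27G01 and too large for Kenyon cells. The class-by-training F test used all 14 groups, the comparison of its Kenyon cell part the 4 Kenyon cell groups. Neurons were set against whole flies of the 7 drivers with control libraries alone. Levels are given as mean CPM ± SD over libraries, computed from the summed deposited counts, and log2 fold changes with their SE. Where a side holds several groups, its mean and SD weigh every library alike, whereas the fold change and the number of libraries above the other side weigh every group alike. Means in CPM and log2 fold changes weigh libraries differently, so they need not match. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts in the group. Floors cover counting error alone, since amplified reads are not independent molecules.

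Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over lists and comparisons of a family. The lists, the comparisons, the main tests, most alternatives and the rule for naming genes were set before the data were examined. Of the lists, 21 had tested members. A list of mitochondrially encoded genes had none, and no result is given for it. In training comparisons the named genes were up to 10 higher and 10 lower with the smallest p among those past the threshold, with list members past it, or the 3 genes with the smallest p where fewer than 3 passed; 1 gene that this rule selects is not reported here. In the other comparisons they were taken from the 10 largest log2 fold changes in each direction past the threshold with at least 10 CPM in the higher group, and from list members past it. The markers mub, rut and Pka-C1 in the comparison of Kenyon cell classes and CG31675 there were named after their values were seen.

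The tests were tried on simulated counts with 200 genes changed 2-fold, 4-fold or 16-fold at the real means, spreads and library sizes. For training in gamma Kenyon cells, 50.7%, 86.6% and 100% of the changed genes were recovered over 7710 genes. In alpha/beta Kenyon cells the shares were 10.8%, 47.7% and 86% over 6958 genes, and in V2 4.62%, 47.6% and 57.1% over 6950. DAL gave 0%, 3.17% and 38.6% over 6549 genes, V3 0%, 11.5% and 41.8% over 6418, 3-86 0%, 3.28% and 25.8% over 6197, and R27G01 0%, 7.27% and 22.8% over 5089. The class-by-training F test, with only DAL trained libraries changed, recovered 0%, 1.56% and 7.58% over 9736 genes. Kenyon cells against other neurons gave 10.4%, 29.2% and 69.2% over 9051 genes, and alpha/beta against gamma 0%, 3.03% and 31.8% over 9052. Unchanged genes made up 15 of 86 edgeR calls for Kenyon cells against other neurons and 21 of 151 for neurons against whole flies. Each class against the others gave 9 of 61 in DAL, 15 of 78 in gamma and 12 of 67 in alpha/beta. The shares were 13 of 76 in V2, 9 of 64 in V3, 14 of 67 in 3-86 and 3 of 52 in R27G01. For alpha/beta against gamma they were 0 of 23. A larger share of class calls than the threshold allows may therefore be false.

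Alternatives were the size factors and tests of DESeq2 1.42.0, no filter on low counts, limma's voom with quality weights, a fit of all 14 groups for training, blocks from the sheet's letters and from the title codes, training as an additive term in class comparisons, subtraction of whole flies, other sums of libraries, and leaving out each library. Other splits of the samples were counted, up to 100 per comparison. Permutation tests and correlations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Descriptions of the NP1131 and G386 whole flies (1A, 1B, 2A and 2B) leave open whether A and B are the same flies; they were counted as 4 replicates, and as 2 in the sums. The brain libraries entered no comparison, because the labels give them no group to be set against.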

Results

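RNA was sequenced from neurons of the mushroom body of Drosophila melanogaster, the fruit fly, drawn from living animals into a patch pipette shortly after aversive training with odours. The mushroom body is the brain centre in which flies form olfactory memories. The study sampled 7 classes of neuron, each found by the GFP that a GAL4 driver line expresses in it. Gamma and alpha/beta Kenyon cells are the intrinsic neurons of the mushroom body. DAL, V2, V3, 3-86 and R27G01 are the classes that the series counts as mushroom body output neurons. Trained animals received an odour together with electric shock in 8 spaced blocks, and control animals received the shock before the odour. A library held 4 cells in DAL, V3, 3-86 and R27G01, 12 cells in V2 and over 100 cells in the Kenyon cells. DAL, V2 and V3 had 5 control and 5 trained libraries, both Kenyon cell classes had 6 and 6, 3-86 had 6 and 4, and R27G01 had 4 and 4. Whole flies of the 7 driver lines and of the GFP reporter line gave 27 libraries, with 3 or 4 per genotype, and brains gave 2.

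Total counts, in M reads (1 M is 1e6), ranged from 1.69 to 22.9 in the 72 neuron libraries (median 7.87), from 0.932 to 16.2 in the whole flies (median 5.49), and were 1.33 and 2.27 in the brains. Gamma control libraries detected 9419 ± 424 genes (SD, n = 6) and R27G01 control libraries 6614 ± 534 (SD, n = 4). Nothing in the labels says which libraries came from the same animal, so p-values measure the spread between libraries. The series text speaks of pairs, but the labels do not say which libraries form a pair, and training was tested without pairing. In the 3-86 class, trained library 2 and control library 3 each summed 2 sequencing runs that did not match one another, and counts were repeated without both.

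Neurons were set against whole flies of the same 7 drivers, to see what the pipette samples held relative to the entire animal. All 14 pan-neuronal genes were higher in neurons, also when adjusted over the list alone. The synaptic vesicle gene n-syb reached 1813 ± 533 CPM (counts scaled to a library total of 1e6; SD, n = 37) against 19.99 ± 13.1 in whole flies (SD, n = 24), a log2 fold change of 6.40 ± 0.23 (SE). The neuronal RNA-binding protein gene elav stood at 841 ± 555 CPM against 8.95 ± 5.37, and the active zone gene brp at 702 ± 489 CPM against 3.93 ± 2.88. Dopamine receptor D2R (149 ± 139 against 0.172 ± 0.395 CPM) and diuretic hormone Dh44 (120 ± 132 against 0.357 ± 0.961 CPM) led the genes higher in neurons. Genes of other tissues led the lower side. Cyp4g1, a cytochrome P450 of oenocytes, had 29.65 ± 134.5 CPM in neurons against 22720 ± 13560 in whole flies, and the gut protease gene Jon65Aiv had 4.68 ± 13.1 against 4276 ± 2078. Muscle markers were lower for all 16 members, with myosin heavy chain Mhc at 20.4 ± 36.8 CPM against 836.5 ± 1941. Yolk protein gene Yp1 was lower too but remained abundant in the pipette samples, at 6534 ± 7760 CPM against 22420 ± 12030.

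Of the receptor lists, 8 of 9 nicotinic, 16 of 18 monoamine and muscarinic, and 13 of 14 GABA and glutamate receptor genes were higher in neurons, with 1 of the last lower; the counts adjusted over the list alone were equal. Kenyon cell markers were higher for 17 of 17. Transmitter identity genes counted 11 higher and 1 lower of 15, neuropeptides and their receptors 19 and 3 of 28, ion channels 17 and 3 of 22 (18 and 3 adjusted over the list alone), cAMP and PKA signalling genes 16 and 1 of 18 (17 and 1), memory genes 23 and 3 of 28 (24 and 3), and activity-regulated genes 8 and 0 of 12. Ribosomal protein genes went the other way, with 1 higher and 76 lower of 85 (2 and 76 adjusted over the list alone). The set test called all of these lists, pan-neuronal genes and muscle markers, and with an estimated correlation it lost neuropeptides (adjusted p = 0.058 with an estimated correlation), ribosomal protein genes (adjusted p = 0.531 with an estimated correlation) and muscle markers (adjusted p = 0.209 with an estimated correlation). Phototransduction genes (11 higher and 12 lower of 30), antimicrobial peptide genes (5 and 2 of 16), fat body markers (2 and 4 of 11), hemocyte markers (3 and 0 of 8) and sex-linked marker genes (0 and 3 of 5) were not called as lists; the phototransduction count is not independent evidence, as the study is known to report on that list. Heat-shock genes (12 higher and 5 lower of 17), clock genes (4 and 3 of 8) and glial markers (4 and 3 of 12) were not called either, and with the size factors of DESeq2 their counts became 8 and 5, 3 and 4, and 3 and 5. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3190 genes were higher and 3620 lower of 10549 tested. Those size factors moved the median log2 fold change of all genes by -0.909, which left 2159 genes higher and 5118 lower, so that the higher share fell from 46.8% to 29.7%.

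Kenyon cells were compared with the other 5 classes in control libraries, the question being how the intrinsic neurons differ in general expression. Of 17 Kenyon cell markers fixed beforehand, 16 were higher in Kenyon cells and none was lower (16 adjusted over the list alone). The RNA-binding protein gene mub reached 9180 ± 2036 CPM (SD, n = 12) against 743 ± 485 (SD, n = 25), a log2 fold change of 4.00 ± 0.18 (SE). The adenylyl cyclase gene rut (1907 ± 408 against 162 ± 108 CPM), the protein kinase A subunit gene Pka-C1 (4797 ± 914 against 508.5 ± 245 CPM) and the Pax6 gene ey (447 ± 158 against 10.5 ± 18.6 CPM) were higher in 12 of 12 libraries. Monoamine and muscarinic receptor genes were higher for 11 of 18 members (11 adjusted over the list alone), among them the dopamine receptor genes DopR (792 ± 133 against 189 ± 132 CPM) and DopR2 (598 ± 95.6 against 39.9 ± 43.7 CPM). Ion channel genes were higher for 11 of 22 members, with 13 adjusted over the list alone. The activity-regulated nuclear receptor gene Hr38 stood at 1038 ± 469 CPM against 73.7 ± 76.3.

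Genes lower in Kenyon cells included markers of other tissues and the ribosome. Kenyon cell libraries held over 100 cells and the others 4 or 12, so cell type and cell number cannot be told apart here. All 9 fat body markers were lower (9 adjusted over the list alone), with Yp1 at 195 ± 178 CPM (SD, n = 12) against 9577 ± 7783 (SD, n = 25) and the storage protein gene Lsp2 at 3.25 ± 4.55 against 270 ± 391. Antimicrobial peptide genes were lower for 10 of 13 members and hemocyte markers for 6 of 8, each with the same number adjusted over the list alone. Ribosomal protein genes were lower for 82 of 86 members (82 adjusted over the list alone), with RpL32 at 250 ± 70.7 CPM against 760 ± 501 (log2 fold change -1.36 ± 0.24). Phototransduction genes counted 6 higher and 11 lower of 30 (6 and 12 adjusted over the list alone), with ninaE, the main rhodopsin, at 19.2 ± 27.5 CPM against 1660 ± 2209; the study is known to report on this list, so its direction is not independent evidence. The neuropeptide gene Ccap had 11.1 ± 25.0 CPM and 0 counts in the other classes, with counts in 7 of 12 libraries, and CG15539 had 60.6 ± 26.6 CPM against 0.926 ± 2.67. edgeR called 1605 genes higher and 1307 lower of 9168 tested at an adjusted p under 0.05. The set test called 13 of 21 lists, 2 of which held with an estimated correlation: Kenyon cell markers (adjusted p = 0.0149 with an estimated correlation) and fat body markers (adjusted p = 0.0188 with an estimated correlation). For ribosomal protein genes that value was adjusted p = 0.186, for antimicrobial peptide genes 0.213, for monoamine and muscarinic receptors 0.208, for hemocyte markers 0.236, and for phototransduction genes and ion channels 0.287. With DESeq2 1640 genes were higher and 1700 lower. Once each class was taken relative to the whole flies of its driver, 643 genes were higher and 1078 lower. DopR2, Ccap and CG15539 no longer passed there (log2 fold changes 4.10, 6.78 and 10.32, adjusted p = 1 each). Their log2 fold changes stayed large, so a lost call does not by itself show that genetic background accounts for a difference.

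The 2 Kenyon cell classes were called different in 2 genes when set against each other. In simulated counts this comparison recovered 0%, 3.03% and 31.8% of genes changed 2-fold, 4-fold and 16-fold. The low number therefore does not show that the classes are alike. Ubx, a Hox gene of the thorax and abdomen, had 412 ± 216 CPM in alpha/beta control libraries (SD, n = 6) against 0.385 ± 0.698 in gamma (SD, n = 6), a log2 fold change of 10.17 ± 0.93 (SE) with adjusted p = 7.02e-09 by edgeR. The RNA-binding protein gene CG17838 had 398 ± 136 CPM against 95.1 ± 21.6 (log2 fold change 2.21 ± 0.39, adjusted p = 0.00371). Both were higher in 6 of 6 alpha/beta libraries. CG31675 had 0 counts in alpha/beta and 24.4 ± 18.3 CPM in gamma, and did not pass (adjusted p = 0.111), though it passed in 5 alternatives, DESeq2 (adjusted p = 0.0114) and training as an additive term (adjusted p = 0.00433) among them. The markers mub (9221 ± 1668 and 9139 ± 2517 CPM), rut (2075 ± 315 and 1739 ± 447 CPM) and Pka-C1 (4884 ± 923 and 4709 ± 985 CPM) were not called different. Heat-shock genes were lower in alpha/beta for 0 of 17 members over all genes and for 7 adjusted over the list alone, and the set test called the list (adjusted p = 8.2e-05, or adjusted p = 0.236 with an estimated correlation). This rested on 1 library, gamma control library 3, left out after seeing the data. Without it 0 members passed adjusted over the list alone. The median log2 fold change went from -2.665 to 0.16, and the set test gave an unadjusted p = 0.432. DESeq2 called 73 genes, and a fit of both Kenyon cell groups alone, chosen after seeing the data, called 118, in each case with both genes among them. Relative to whole flies of the same drivers 5 genes were called, Ubx but not CG17838 (log2 fold change 0.78, adjusted p = 1).

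DAL neurons were then set against the mean of the other 6 classes, the first of 7 such comparisons in control libraries that ask which genes set a class apart. Libraries held 4, 12 or over 100 cells depending on the class, and these comparisons do not separate class from cell number. Title codes differ by class as well. Their first digits were 2 or 4 in R27G01 controls and 4 to 6 in 3-86 controls, against 8 to 12 in the others. For R27G01 and 3-86, class and code therefore cannot be told apart. The comparisons also share 1 spread per gene, so p-values may be too small where the libraries of a class spread more widely. The neuropeptide precursor gene Nplp1 had 8663 ± 6586 CPM (SD, n = 5) against 208 ± 199 (SD, n = 32), a log2 fold change of 5.71 ± 0.29 (SE), and npf, the fly neuropeptide F gene, had 690 ± 1280 against 5.205 ± 16.8. They were among 3 of 26 neuropeptide list members that were higher (3 adjusted over the list alone), and the set test did not call that list (adjusted p = 0.0845). Nplp1 and npf were higher in 5 of 5 libraries, and the peptide gene Trissin, at 5398 ± 12020 CPM against 43.4 ± 205, in 2 of 5; its call was lost without DAL control library 2 (log2 fold change 2.79), and DESeq2 gave it no adjusted p. The blue-light receptor gene cry had 74.4 ± 68.0 CPM against 6.24 ± 8.09. Phototransduction genes, which are not independent evidence of direction, counted 15 higher and 1 lower of 30 (18 and 1 adjusted over the list alone), with ninaE at 2816 ± 2098 CPM against 864 ± 1839, higher in 4 of 5 libraries. Fat body markers were higher for 7 of 9 members, hemocyte markers for 6 of 8 and ribosomal protein genes for 61 of 86, and Kenyon cell markers were lower for 5 of 17. These counts were 8, 7, 78 and 9 adjusted over the list alone. Both Kenyon cell classes are part of the average used here, so lower Kenyon cell markers do not by themselves set DAL apart from the other output neurons. edgeR called 858 genes higher and 125 lower at an adjusted p under 0.05. None of these lists kept its call with an estimated correlation (adjusted p = 0.138 for phototransduction, 0.13 for fat body, 0.191 for hemocyte, 0.236 for ribosomal protein genes and 0.0553 for Kenyon cell markers). Without DAL control library 4 the total was 620 genes, and relative to whole flies of the same drivers it was 61. The latter fit lost npf, cry, ninaE and Trissin (adjusted p = 0.106, 0.257, 0.178 and 1).

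Gamma Kenyon cells, set against the other 6 classes, had CG31675 at 24.4 ± 18.3 CPM (SD, n = 6) against 0.00642 ± 0.03575 (SD, n = 31) and CG17639 at 182 ± 77.1 against 8.28 ± 15.4. The short neuropeptide F gene sNPF reached 3119 ± 491 CPM against 890 ± 960, and the zinc-finger gene ab 608 ± 99.1 against 192 ± 121, with log2 fold changes of 2.82 ± 0.74 and 1.92 ± 0.37 (SE). Ubx was lower, by a log2 fold change of -9.77 ± 0.89, and the antimicrobial peptide gene AttC was at least 2680-fold lower, with 0 counts in gamma. Kenyon cell markers were higher for 15 of 17 members (16 adjusted over the list alone) and fat body markers lower for 7 of 9 (8 adjusted over the list alone; adjusted p = 0.0149 and 0.0188 with an estimated correlation). Heat-shock genes were higher for 8 of 17 (10 and 1 lower adjusted over the list alone), with a median log2 fold change of 2.04, while the set test pointed down without a call (adjusted p = 0.412). Without gamma control library 3, left out after seeing the data, 0 members were higher and 1 lower over all genes, with a median of -0.98. Hsp70Aa, at 440 ± 1052 CPM against 42.1 ± 53.6, was above the other classes in 1 of 6 libraries, and without that one, the same library, its log2 fold change was -1.70. edgeR called 1509 genes, 597 of them lower, at an adjusted p under 0.05. DESeq2 called 727 higher and 1066 lower. Relative to whole flies of the same drivers, 202 were higher and 344 lower. Calls were lost there for sNPF, ab, AttC and Hsp70Aa (adjusted p = 0.105, 0.0728, 0.441 and 0.109).

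Alpha/beta Kenyon cells were higher than the other 6 classes for 15 of 17 Kenyon cell markers (16 adjusted over the list alone), 11 of 18 monoamine and muscarinic receptor genes and 9 of 22 ion channel genes (11 of each adjusted over the list alone). The octopamine receptor gene Oamb had 257 ± 66.2 CPM (SD, n = 6) against 56.5 ± 49.6 (SD, n = 31), the cell adhesion gene Fas2 501 ± 142 against 161 ± 121 and the potassium channel gene Sh 5684 ± 1392 against 2042 ± 1161. Log2 fold changes were 2.96 ± 0.65, 2.17 ± 0.25 and 1.90 ± 0.22 (SE). CG32440 was at least 1240-fold higher, with 0 counts in the other classes. Ccap, at 14.2 ± 34.8 CPM against 1.55 ± 5.79, was above their mean in 1 of 6 libraries. Fat body markers were lower for 8 of 9 members (9 adjusted over the list alone). edgeR called 1071 genes higher and 665 lower at an adjusted p under 0.05. Kenyon cell and fat body markers kept their set call with an estimated correlation (adjusted p = 0.0149 and 0.0188), and monoamine and muscarinic receptors and ion channels did not (adjusted p = 0.174 and 0.216 with an estimated correlation). DESeq2 called 977 higher and 1047 lower. Relative to whole flies, 161 genes were higher and 641 lower. Sh (log2 fold change 0.86, adjusted p = 0.444), Oamb (3.65, adjusted p = 0.12), CG32440 and Ccap (adjusted p = 1 each) no longer passed.

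V2 neurons, with 12 cells to a library, stood apart by few genes. Dopamine transporter DAT had 288 ± 323 CPM (SD, n = 5) against 57.4 ± 65.0 (SD, n = 32) and tyrosine hydroxylase ple, the first enzyme of dopamine synthesis, 281 ± 362 against 33.9 ± 61.8, with log2 fold changes of 4.34 ± 0.79 and 3.22 ± 0.93 (SE). They were above the mean of the other classes in 3 and 4 of 5 libraries, and ple lost its call without V2 control library 1 (2.23) or 4 (2.96), or gamma control library 1 (3.20), and with the size factors of DESeq2 (3.125, adjusted p = 0.0503). The forkhead gene fd102C had 92.4 ± 67.3 CPM against 9.29 ± 18.8, and the zinc-finger gene opa 28.3 ± 24.5 against 1.24 ± 3.05. LanB1, a laminin subunit gene, was at least 383-fold lower with 0 counts in V2. Ribosomal protein genes were lower for 68 of 86 members (82 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). edgeR called 248 genes higher and 144 lower at an adjusted p under 0.05. The total was 256 without V2 control library 1 and 221 without V2 control library 3, while DESeq2 called 857 and the fit relative to whole flies 5. DESeq2 also turned the balance, with 287 higher and 570 lower. Relative to whole flies DAT (log2 fold change 4.18, adjusted p = 0.29), ple (adjusted p = 0.58), fd102C and opa (adjusted p = 1 each) no longer passed.

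V3 neurons carried the genes of octopamine synthesis. The vesicular monoamine transporter gene Vmat reached 17220 ± 19260 CPM (SD, n = 5) against 200.5 ± 498 (SD, n = 32), tyramine beta-hydroxylase Tbh 625 ± 941 against 7.92 ± 14.8, and tyrosine decarboxylase Tdc2 364 ± 381 against 8.755 ± 33.4. Log2 fold changes were 7.92 ± 1.00, 8.12 ± 0.97 and 7.89 ± 0.96 (SE), and each was higher in 5 of 5 libraries. Relative to whole flies of the same drivers the 3 no longer passed, at 8.09, 7.62 and 8.89 (adjusted p = 0.172, 0.161 and 1). These were the 3 of 15 transmitter identity genes that passed (4 adjusted over the list alone), and the list kept its call with an estimated correlation (adjusted p = 0.0484). The homeobox gene ems had 39.1 ± 45.1 CPM against 0.0194 ± 0.0494. The peptide genes capa (270 ± 576 against 1.5 ± 7.46 CPM) and Pdf (71.7 ± 160 against 0.862 ± 2.37 CPM) were higher in 2 and 1 of 5 libraries, and without V3 control library 1 the log2 fold change of Pdf was -0.84; DESeq2 gave Pdf no adjusted p. Kenyon cell markers were lower for 6 of 17 members (11 adjusted over the list alone; adjusted p = 0.0149 with an estimated correlation), with dac at 1.29 ± 1.83 CPM against 316 ± 235. The average they were set against includes both Kenyon cell classes, so this list does not by itself set V3 apart from the other output neurons. Phototransduction genes, not independent evidence of direction, counted 13 higher and 2 lower of 30 (17 and 2 adjusted over the list alone; adjusted p = 0.394 with an estimated correlation), and ninaE exceeded the other classes' mean in 1 of 5 libraries, with no call without it (V3 control library 5; log2 fold change 0.81). edgeR called 499 genes higher and 33 lower at an adjusted p under 0.05. Without V3 control library 4 the total was 298, and relative to whole flies it was 3. The latter fit also lost ems, capa, Pdf, dac and ninaE (adjusted p = 1, 0.172, 0.396, 0.157 and 0.935).

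The 3-86 neurons expressed VGlut, the vesicular glutamate transporter, at 9298 ± 3783 CPM (SD, n = 6) against 2035 ± 2892 (SD, n = 31), a log2 fold change of 2.82 ± 0.32 (SE) seen in 6 of 6 libraries. The insulin-like peptide gene Ilp5 had 8121 ± 19130 CPM against 15.4 ± 72.5 and Ilp3 733 ± 1538 against 1.125 ± 4.59, higher in 4 and 5 of 6 libraries, with log2 fold changes of 11.87 ± 1.37 and 11.74 ± 1.26. The non-coding gene CR43211 was at least 1760-fold higher, from 0 counts elsewhere. Muscle markers were higher for 11 of 16 members, among them Act57B (113 ± 105 against 17.5 ± 45.5 CPM) and Mlc2 (235.5 ± 284 against 33.6 ± 60.7 CPM). Antimicrobial peptide genes were higher for 10 of 13, fat body markers for 8 of 9, ribosomal protein genes for 81 of 86, and phototransduction genes, not independent evidence of direction, for 16 with 3 lower of 30. Adjusted over the list alone, the higher counts were 11 for muscle, 12 for antimicrobial peptide, 8 for fat body, 81 for ribosomal protein and 17 for phototransduction genes. Pan-neuronal genes were lower for 6 of 14 members (6 adjusted over the list alone), with elav at 351 ± 240.5 CPM against 936 ± 551, though its log2 fold change relative to whole flies was 0.28. edgeR called 1415 genes higher and 519 lower at an adjusted p under 0.05. With an estimated correlation the adjusted p was 0.149 for muscle, 0.255 for antimicrobial peptide, 0.213 for fat body, 0.236 for ribosomal protein and 0.213 for phototransduction genes, so none of these lists kept its call. Without control library 3, whose runs did not match, and relative to whole flies, the totals were 1834 and 863. In the latter Ilp5 (adjusted p = 1) and Mlc2 (adjusted p = 0.157) no longer passed.

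R27G01 neurons shared high VGlut, at 8655 ± 3280 CPM (SD, n = 4) against 2554 ± 3634 (SD, n = 33), with a log2 fold change of 2.82 ± 0.36 (SE) in 4 of 4 libraries. Antimicrobial peptide genes were higher for 12 of 13 members: Mtk had 899 ± 1330 CPM against 71.2 ± 133 in 4 of 4 libraries and Drs 4376 ± 8255 against 169 ± 370 in 3 of 4. Fat body markers were higher for 7 of 9, with Yp1 at 18090 ± 8330 CPM against 5134 ± 6521, and ribosomal protein genes for 82 of 86, with the same counts adjusted over the list alone. Ion channel genes were lower for 7 of 22 (8 adjusted over the list alone), including Sh (814 ± 407 against 2853 ± 1781 CPM) and para (355 ± 230 against 1200 ± 840 CPM). Chromatin remodelling gene Iswi was at least 353-fold lower and muscarinic acetylcholine receptor gene CG7918 at least 940-fold lower, both with 0 counts in R27G01; CG7918 lost its call without 3-86 control library 5 (log2 fold change -9.90). edgeR called 1014 genes higher and 538 lower at an adjusted p under 0.05. The set calls were lost with an estimated correlation (adjusted p = 0.186 for antimicrobial peptide, 0.117 for fat body, 0.14 for ribosomal protein and 0.394 for ion channel genes). With DESeq2 965 were higher and 1212 lower. Relative to whole flies, 441 genes were higher and 463 lower, and Mtk no longer passed (adjusted p = 0.0741).

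**Figure D1:**
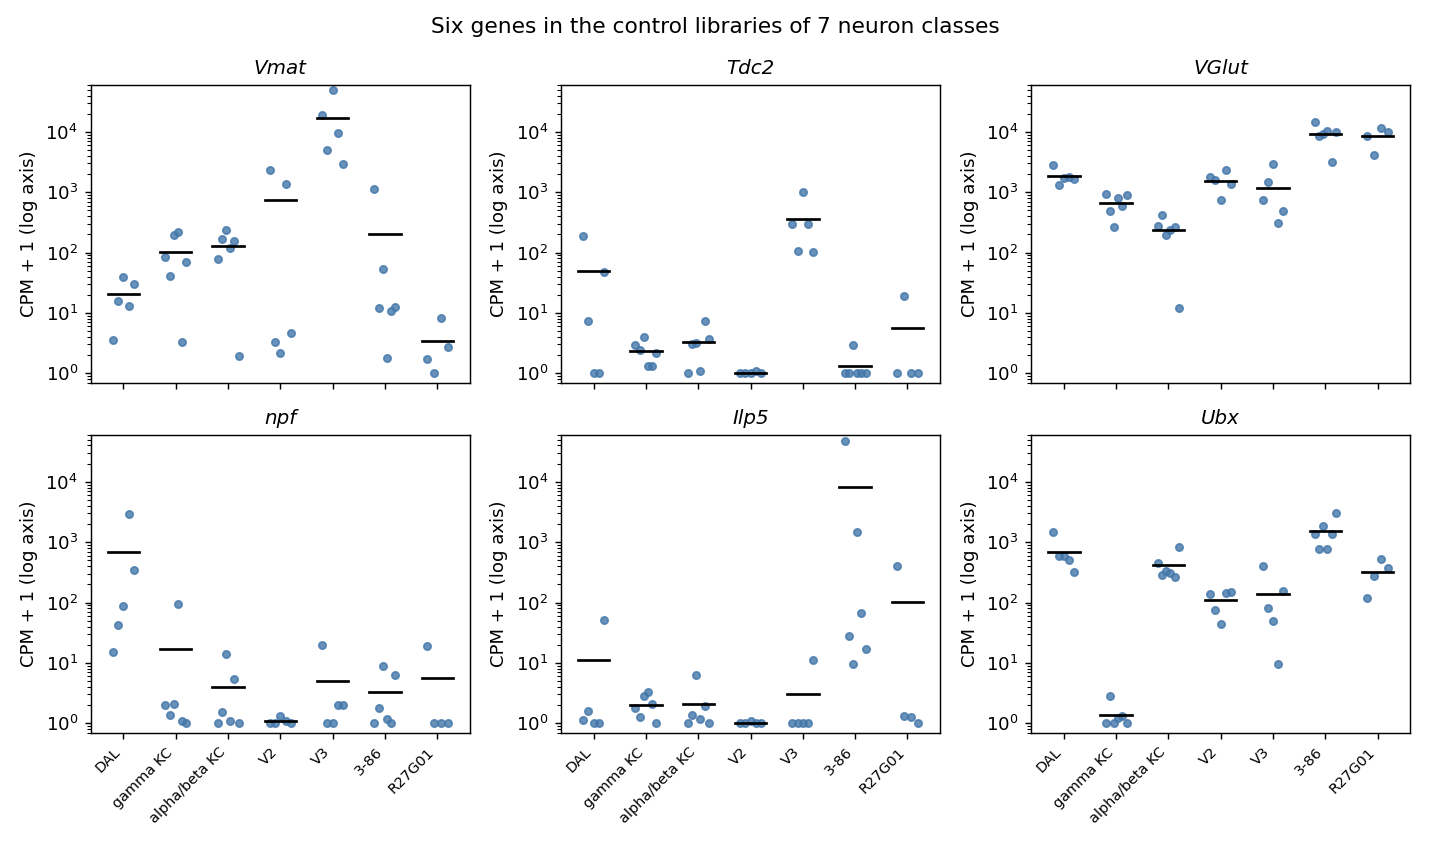
CPM plus 1 (log axis) of Vmat, Tdc2, VGlut, npf, Ilp5 and Ubx in the control libraries of 7 neuron classes; each point is a library and each line the class mean. Vmat and Tdc2 stand highest in V3, VGlut in 3-86 and R27G01, and Ubx is near 0 only in gamma Kenyon cells.

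**Figure D2:**
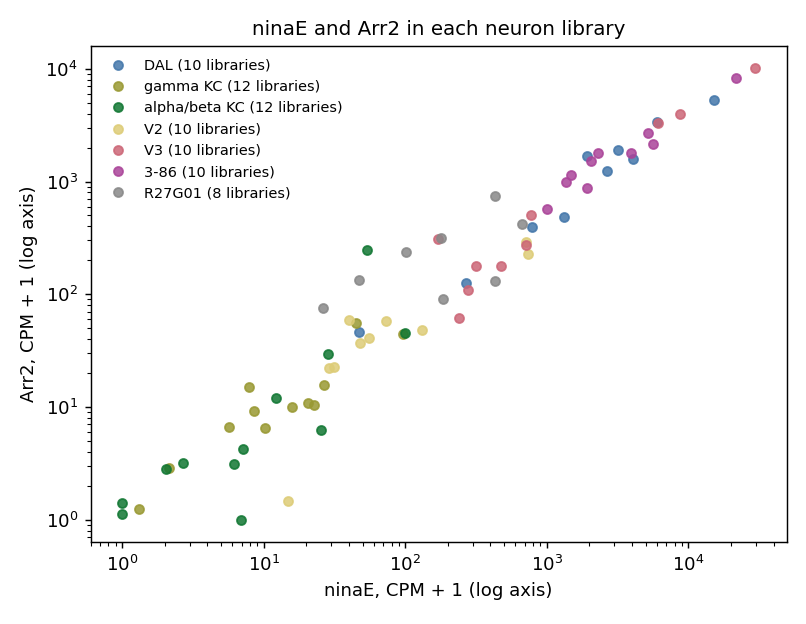
CPM plus 1 of ninaE (horizontal, log axis) and Arr2 (vertical, log axis) in the neuron libraries, coloured by class; each point is a library. DAL, V3 and 3-86 libraries reach ninaE levels of 15300, 29500 and 21800 CPM, and Arr2 rises with ninaE.

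Training was tested within each class by comparing trained with control libraries. No gene passed an adjusted p of 0.05 in any of the 7 classes by edgeR's quasi-likelihood test, so the genes named here are among the 3 with the smallest p in each class, and their values differed by less than the adjusted test required. In DAL, mim had 151 CPM in trained against 32.1 in control libraries, IM23, an immune-induced peptide gene, 136 ± 97.7 against 793 ± 662 (SD, n = 5 and 5), and Rcd7 13.3 against 0.01155, all with adjusted p = 1. For gamma Kenyon cells the genes were CG33639 (19.9 ± 6.45 against 48.4 ± 16.2 CPM, SD, n = 6 and 6; log2 fold change -1.43 ± 0.26, adjusted p = 0.172), CG12269 (70.7 against 25.3 CPM, adjusted p = 0.512) and CG4766 (11.6 against 30.3 CPM). For alpha/beta Kenyon cells they were Hr38, an activity-regulated nuclear receptor gene (1388 ± 456 against 755 ± 192.5 CPM, SD, n = 6 and 6; log2 fold change 0.85 ± 0.23, adjusted p = 0.999, above the control mean in 5 of 6 trained libraries) and CG17108 (17.2 against 0.980 CPM). V2 had the Pax6 gene toy (572 ± 162 against 153 ± 67.4 CPM, SD, n = 5 and 5; log2 fold change 1.85 ± 0.31, adjusted p = 0.164, above the control mean in 5 of 5), Ir68a (14.6 against 0.0154 CPM, adjusted p = 0.406) and the peptide-processing protease gene amon (532 against 1041 CPM, adjusted p = 0.406). In V3 the genes were CG6179 (0.0377 against 26.6 CPM), Cyp4e3 (13.9 against 0.0888 CPM) and beat-Vb (104 against 19.0 CPM), in 3-86 Drl-2 (0.248 against 82.8 CPM), the Pdh gene (1707 against 381 CPM) and AP-47 (2.40 against 117 CPM), and in R27G01 fau (117 against 0.844 CPM), Gclm (1.79 against 117 CPM) and pix (70.9 against 365 CPM), with adjusted p = 1, 0.999 and 1 in these classes.

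Counts at an unadjusted p under 0.05 were 136 of 6953 genes in DAL, 440 of 7840 in gamma, 198 of 7228 in alpha/beta, 393 of 7281 in V2, 100 of 6858 in V3, 185 of 6692 in 3-86 and 133 of 5548 in R27G01. DESeq2 called 5 genes in DAL, 5 in gamma, 0 in alpha/beta, 32 in V2, 3 in V3, 20 in 3-86 and 37 in R27G01. More were lower than higher in V2 (18 and 14), 3-86 (20 and 0) and R27G01 (32 and 5). Of the genes named above these held Rcd7 in DAL, CG33639, CG12269 and CG4766 in gamma, toy, Ir68a and amon in V2, CG6179 and Cyp4e3 in V3, Drl-2 and AP-47 in 3-86, and fau, Gclm and pix in R27G01. In simulated counts, unchanged genes made up 25 of 83 DESeq2 calls in DAL, 29 of 196 in gamma and 23 of 134 in alpha/beta. They made up 24 of 113 in V2, 29 of 85 in V3, 60 of 95 in 3-86 and 61 of 95 in R27G01. For edgeR they were 5 of 23 in 3-86 and 4 of 21 in R27G01. Many DESeq2 calls may therefore be false, above all in 3-86 and R27G01. limma's voom with quality weights called 2 genes in V2, toy and Ir68a, and 0 in each other class. The gene toy also passed without a filter on low counts (adjusted p = 0.0142). Without gamma control library 2 edgeR called 4 genes in gamma, CG33639 (adjusted p = 0.00824) and CG12269 (adjusted p = 0.039) among them, and leaving out any other library gave 0 calls in each class. With the full code of the titles as a block, an alternative chosen after seeing the data, 1 gene was called in gamma. A single fit of all 14 neuron groups, which lends every class 1 spread, called 2 genes in DAL, 96 in 3-86, 427 in R27G01 and 0 in the other classes, with 60 lower in 3-86 and 356 in R27G01. Trained R27G01 libraries also detected fewer genes in all, 5728.5 ± 321 against 6614 ± 534 in controls (SD, n = 4 and 4), and lower detection was not separated from lower expression.

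**Figure D3:**
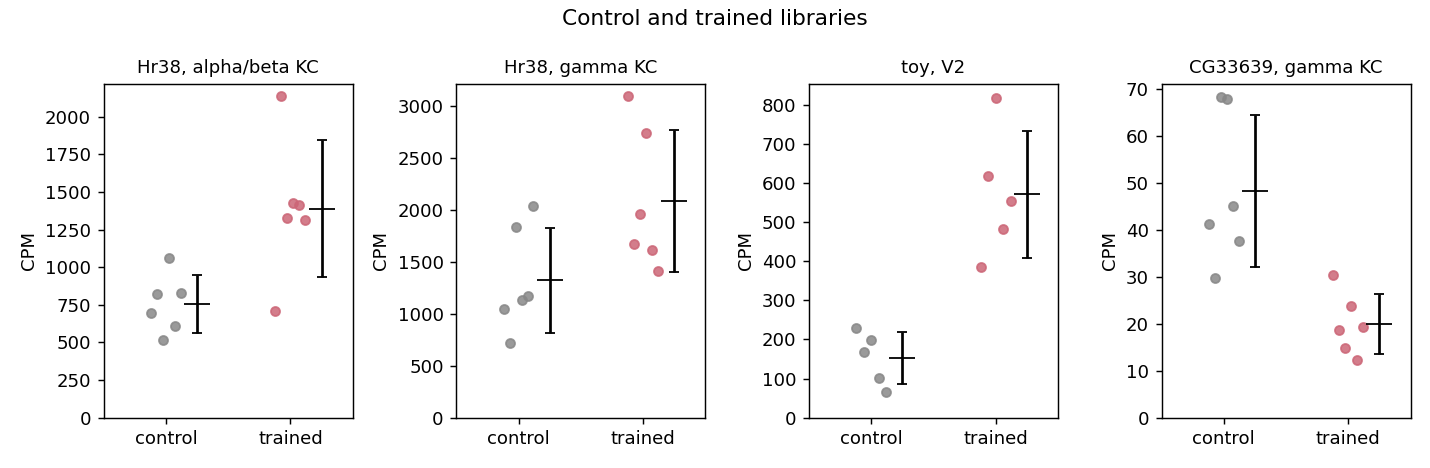
CPM of Hr38 in alpha/beta and gamma Kenyon cells, toy in V2 and CG33639 in gamma Kenyon cells; each point is a control or trained library, and bars give the mean and SD. Hr38 in alpha/beta cells averaged 1388 after training and 755 in controls, and no gene shown passed adjustment over all genes.

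No list member passed over all genes in the training comparisons either. In alpha/beta Kenyon cells, 9 of 11 activity-regulated genes had positive log2 fold changes, with Hr38 past the threshold adjusted over the list alone. The set test called that list (adjusted p = 0.00648, or adjusted p = 0.412 with an estimated correlation). It also called heat-shock genes, 15 of 17 positive with a median of 2.79 (adjusted p = 5.71e-09, or 0.621 with an estimated correlation). Trained libraries 1, 2 and 3 carried this, with a mean log2 CPM over the list of 7.98, 6.09 and 6.10, while the others (4.01 to 4.75) lay within the controls (3.36 to 5.79). Library 1 is the smallest of the neuron libraries, with 1.69 M counts and 5558 genes detected. Also called were fat body markers, 6 of 7 positive (adjusted p = 4.41e-06, or 0.621 with an estimated correlation), of which Lsp2, Rfabg, Yp1, Yp2 and Yp3 passed adjusted over the list alone. In V2, 8 of 11 activity-regulated genes were positive, with the early growth response gene sr past the list-alone threshold (set test adjusted p = 0.0182, or 0.621 with an estimated correlation). In gamma, 16 of 17 monoamine and muscarinic receptor genes were negative (adjusted p = 0.00169, or 0.997 with an estimated correlation). Muscle markers were positive for 14 of 16 members in 3-86 (adjusted p = 1.7e-05, or 0.621 with an estimated correlation), and hemocyte markers were negative for 7 of 7 in V3 (adjusted p = 0.00648, or 0.997 with an estimated correlation). Ribosomal protein genes were called up in alpha/beta, V3, 3-86 and R27G01 and down in DAL, each with adjusted p = 0.997 with an estimated correlation. In total 26 of 168 list tests passed with the preset correlation and 0 with an estimated one.

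Whether training acted differently between classes was tested directly, over all 14 groups. The genes with the smallest p were the ones named. CG9975 had 13.2 and 0 CPM in DAL control and trained libraries, 80.4 and 83.8 in gamma, 11.5 and 56.0 in V2, and 0 and 9.12 in 3-86 (adjusted p = 0.000159). Hr51, a nuclear receptor gene, had 63.1 and 65.4 CPM in gamma, 0.0148 and 18.7 in V2 and 0 and 2.425 in R27G01 (adjusted p = 0.00802). Several others were at 0 or nearly so in trained R27G01 libraries, which detected fewer genes than their controls: CG32262 went from 17.3 to 0 CPM, CG34420 from 19.65 to 0, CG15432 from 21.5 to 0, Gnf1 from 11.5 to 0 and the chromatin gene Chro from 24.8 to 0.149. Among list members, Oamb, the histidine decarboxylase gene Hdc, CG7918, Ast, Pdf and Takr86C passed. Of the 122 genes called, 81.1% had no reads in at least 1 of the 14 groups. The F test of the class-by-training terms called 122 of 9847 genes by edgeR, and limma's voom with quality weights, added after seeing the data, 9, of which 6 were shared. A single library changed the total by more than 1.5 times in 8 cases: 42 and 45 without R27G01 trained libraries 2 and 1, 64 and 80 without gamma control libraries 4 and 5, 74 without 3-86 trained library 4, 78 without alpha/beta control library 6, and 187 and 228 without 3-86 control library 3 and 3-86 trained library 2, the ones with mismatched runs. Without both of these the count was 275, with 110 shared. In 15 of 40 splits of the libraries, the real one included, the count was as large.

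Between the Kenyon cell classes alone, the training effect differed for 0 of 8236 genes by edgeR (377 at an unadjusted p under 0.05), and DESeq2 called 15, the next 3 among them. GRHR, Reg-2 and CG10581 had the smallest p, with log2 differences of 10.65 ± 2.22, 8.78 ± 1.92 and -8.17 ± 1.75 (SE) between alpha/beta and gamma and adjusted p = 0.217 each. Heat-shock genes were more positive in alpha/beta for 17 of 17 members and fat body markers for 8 of 8, the latter with Lsp2, Yp1, Yp2 and Yp3 past the threshold adjusted over the list alone. The set test gave adjusted p = 3.78e-06 and 1.27e-05 for the pair, and adjusted p = 0.997 and 0.621 with an estimated correlation. Gamma control library 3 carried most of the heat-shock difference. Without it, a choice made after seeing the data, the median log2 difference fell from 4.215 to 0.37, with 16 of 17 positive and an unadjusted set p = 0.000261. A fit of both classes with training as one additive term, chosen after seeing the data, called 0 genes; Hr38 had a log2 fold change of 0.66 ± 0.19 (SE) there, with adjusted p = 0.994.

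Whole flies were collected to account for differences of genetic background. Flies of c739-GAL4, the alpha/beta driver, had more muscle transcripts than flies of NP1131-GAL4, the gamma driver: 11 of 16 muscle markers were higher (16 adjusted over the list alone), with the flight muscle actin gene Act88F at 1932 ± 3300 CPM (SD, n = 3) against 6.24 ± 2.03 (SD, n = 4) and fln at 1082 ± 1853 against 2.22 ± 0.733. Both were above the NP1131 mean in 2 of 3 libraries. The NP1131 descriptions leave open whether the 4 libraries come from 2 sets of flies. Summed accordingly, the comparison called 65 genes, and Act88F (adjusted p = 0.294), fln (adjusted p = 0.301) and Yp1 (adjusted p = 0.088) no longer passed. Without c739 library 1 their log2 fold changes were 2.50 and 2.90 and that of Yp1 -1.21, with no call. Act88F and fln also lost their calls without any 1 of the 4 NP1131 libraries, at 8.70 to 9.02 and 9.39 to 9.68. Yolk protein genes were lower, Yp1 at 7562 ± 4941 CPM against 26450 ± 2983 and Yp2 at 3003 ± 1428 against 20900 ± 3053. Digestive lysozyme gene LysD (7.02 ± 2.60 against 347 ± 153 CPM) and LysB (25.45 ± 7.144 against 595 ± 250 CPM) were lower in 3 of 3 libraries, and the odorant-binding protein gene Obp57a was at least 295-fold lower. The muscle list lost its call with an estimated correlation (adjusted p = 0.266). edgeR called 330 genes higher and 171 lower of 9521 at an adjusted p under 0.05. That total became 133 without c739 library 1, 1086 without c739 library 2, 774 without DAL-GAL4 library 3, and 208, 184 and 246 without NP1131 libraries 1, 3 and 4. Over all 8 genotypes 2998 of 9521 genes differed by the F test, and over the 7 driver lines, a choice made after seeing the data, 1364.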

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

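Of the tests below, those of the 3 weighed patterns (the class-by-training genes, photoreceptor transcripts and Ubx) were chosen, and their bounds set, only after the results were seen, as was the look at title codes within splits; the counts over other splits of the samples were planned.

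Single libraries stood far from the others of their group in 10 of 86 groups of values, by a gap test that gives about 1 in 20 by chance for normal values. CPM values of amplified libraries need not be normal, and the genes were picked by their training p in the same libraries. An excess over chance is therefore not shown. Total counts, in M reads, were 17.31 in DAL control library 5, above 7.4 to 8.787 in the others, and 2.782 in NP1131 whole-fly library 3, below 4.226 to 4.489. The 10 most abundant genes took 23.46% of counts in R27G01 trained library 4, against 13.18% to 14.45%. Among the genes named for training, CG12269 had 55.61 CPM in gamma control library 2, CG17108 62.89 CPM in alpha/beta trained library 5, and Cyp4e3 47.5 CPM in V3 trained library 2. The others were beat-Vb at 50.55 CPM in V3 control library 2, AP-47 at 404 CPM in 3-86 control library 6, fau at 258.3 CPM in R27G01 trained library 2 and Gclm at 5.344 CPM in R27G01 trained library 3. None of these genes passed the adjusted training test.

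Brain libraries, which no comparison used, held neuronal transcripts above whole flies of the reporter line. Median levels over a list were 996 against 42.2 CPM for pan-neuronal genes, 359 against 16.9 CPM for Kenyon cell markers and 48.7 against 27.8 CPM for glial markers.

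The training effect differed between classes for 122 genes by edgeR's F test, led by CG9975 (adjusted p = 0.000159), Hr51 (0.00802) and CG32262 (0.0125), with CG34420, Try29F, Gnf1, CG1105, Chro, CG15432 and fd102C at 0.0215 each. Chance is not excluded as the reason for the number: 15 of 40 splits of the libraries gave as many, and the highest of the others gave 365. Of the 122 genes, 81.1% had no reads in at least 1 group, against 44% on average in 10000 random sets of the same level (highest 54.9%; p = 1e-04, the smallest they can give). That share decides nothing, since a true on and off effect of training would give it as well. When each library was weighted by its own noise with limma's voom, 6 of the genes passed. A drop of this kind is what 1 spread for libraries of 4 cells and of over 100 cells would give. That fit changed the test as well as the weights, so the drop cannot be put down to the spread alone. DESeq2, also with 1 spread per gene, called 403, with 78 shared. A difference of training effect between classes stays open for single genes, since the F test recovered 7.58% of genes changed 16-fold in simulated data. Those data changed DAL trained libraries alone and held no other differences between classes, so recovery in the real data may differ.

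Photoreceptor transcripts in DAL, V3 and 3-86 libraries varied widely, with ninaE from 45.9 to 15300 CPM in DAL, 170 to 29500 in V3 and 994 to 21800 in 3-86. The tables argue against RNA of the whole animal. At the level that ninaE predicts from whole flies of the same driver, the 10 most abundant whole-fly transcripts reached a median of 5.14%, with Cyp4g1 at 0.00593% and CG12374 at 0.00232%. A bound of 20% for each was exceeded by 3 of the 10, Yp1 (25%), Yp2 (22%) and RpS3A (27.7%), which does not rescue the explanation, since whole-animal RNA would bring Cyp4g1 and CG12374 at the predicted level too. A single source of photoreceptor RNA in varying amounts remains a candidate explanation: over 16 other list members that were higher in a class, the median Pearson r with ninaE within class was 0.799 (permutation p = 0.0001, the smallest that 10000 random orders can give). Not all members followed ninaE: r was -0.71 for rdgC in 3-86, and -0.407 for ninaB and -0.00505 for ninaD in DAL. All other r were positive, and Arr1 and Arr2 had the highest in each class. For Arr2 the r with ninaE was 0.981 in DAL, 0.954 in V3 and 0.961 in 3-86 (n = 10 each). Its permutation p was 1e-05, 0.0003 and 4e-05, adjusted over the 3 to 3e-05, 0.0003 and 6e-05. Spearman's rho was 0.939, 0.806 and 0.952 (permutation p = 0.0002, 0.007 and 0.0001, adjusted 0.0003, 0.007 and 0.0003), and without the 2 libraries farthest from the median r was 0.943, 0.875 and 0.904. In 3-86, trained library 2 and control library 3 share RNA of one origin, so its 10 libraries are not fully independent. The correlation was not repeated without both. Expression at a steady level in the cells of a class cannot be told apart from a single source in varying amounts. Among 500 genes of the same level, the spread of the members lay at a median percentile of 95.2 in DAL, 99 in V3 and 75 in 3-86. The bound of 95 was passed in DAL and V3, but without 1 library each (DAL trained 5, V3 trained 1) the values were 89.8 and 92.2, so single libraries keep this open, and 3-86 lay below the bound. The list is not independent evidence, as the study is known to report on it. The plot of ninaE and Arr2 by library shows the relation.

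Ubx was abundant in 6 of the 7 classes. Control means were 690 CPM in DAL, 412 in alpha/beta, 109 in V2, 139 in V3, 1510 in 3-86 and 322 in R27G01, against 0.385 in gamma. A Ubx sequence in the shared GFP reporter is argued against by that 0.385 CPM, as gamma cells carry the same reporter. RNA of the whole animal is argued against too: it would need at least 58.2% of the RNA (V2), where the 10 abundant whole-fly transcripts of that class gave 3.37%, and the ratio was at least 17.3 in each class. A Ubx sequence in the driver insertions stays open. Whole flies of the 3-86, V2 and alpha/beta drivers held 194 ± 59.3, 188 ± 27.8 and 140 ± 162 CPM of Ubx (SD, n = 4, 3 and 3). Those of the R27G01, gamma, V3 and DAL drivers held 28.5, 7.25, 5.77 and 4.71 CPM, and the reporter line 10.6. Over the 7 drivers Ubx in neurons and in whole flies had a Spearman rho of 0.179 (exact permutation p = 0.713), which 7 values cannot decide. The other Hox genes Antp and abd-A reached at most 4.51 and 0.034 CPM in a class mean, and the brains held 1.5 and 0.44 CPM of Ubx. Expression of Ubx in these neurons may therefore be biological or come from the driver lines, and these data cannot separate the possibilities.

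The real labels gave more genes than any other split of the samples for Kenyon cells against other neurons (2912 genes; highest other split 525). They also did so for DAL 983 (484), gamma 1509 (294) and alpha/beta 1736 (242), each against the other classes. The same held for V2 392 (214), V3 532 (247), 3-86 1934 (467) and R27G01 1552 (161). The real count was also the largest for alpha/beta against gamma (2; highest other 1) and neurons against whole flies (6810; 1246). So it was for the genotypes of whole flies (2998; 649) and c739 against NP1131 flies (501; 3). In each of these 1 split, the real one, was as large, of 40 for neurons against whole flies and of 100 otherwise. Other splits often gave calls too. For a class against the others, 95 (V3) to 98 (3-86) of them did, with medians of 17 (R27G01) to 41 (3-86) genes. Single genes among those counts may therefore be chance calls. Libraries were exchanged over all classes, not between alpha/beta and gamma alone, so chance was not excluded for that pair. For training, counts at an unadjusted p under 0.05 were as large in 62 of 100 splits in DAL (136; highest other 506), 29 in gamma (440; 2110), 50 in alpha/beta (198; 945), 94 in V3 (100; 367), 42 in 3-86 (185; 611), and 9 of 35 in R27G01 (133; 288), so chance was not excluded there. In V2 it was 2 of 100 (393; 454). That is the smallest share among the classes tested for training, and it was not corrected for their number. No V2 gene passed adjustment (smallest adjusted p = 0.164 by edgeR's quasi-likelihood test). Chance was therefore not excluded in V2, nor was an effect of the codes in the titles. All 5 trained libraries share first digits of the code that 3 of 5 controls lack, and the other split as large also had those 3 on the same side. With the code as a block the V2 count fell to 127, so training and code cannot be told apart there. In DAL the same block raised the count from 136 to 396, with 0 calls after adjustment. DAL control libraries 3, 4 and 5 carry a code of 11 that no DAL trained library has, so training and code are not fully separated there either. The DAL splits were counted without that block. Codes were uneven in alpha/beta as well, where first digits of 9 fell on control libraries 1, 3 and 6 and on trained library 4 alone. The block there gave 179 genes, against 198 without it. The training difference between Kenyon cell classes gave 35 of 100 (377; 1253). A split of the gamma libraries with 2 trained libraries among the 6 on one side gave 2110 genes, several times the real count, which points to a structure among those libraries. It did not follow the full codes in the titles, each of which was on both sides of that split; what it follows was not found.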

How the results depend on the processing

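Tests chosen only after the result was seen were voom for the class-by-training genes, fits without the 2 mixed 3-86 libraries, the Kenyon cell groups in a fit of their own, training as an additive term over both of them, DAL, V2 and V3 alone as the other neurons, alpha/beta training without the pair that the sheet does not place, the full title code as a block in gamma, the heat-shock list without gamma control library 3, and the 7 driver genotypes. Over 21 comparisons, 78 of 125 alternative counts lay within 1.5 times the main count and 47 did not; the cause was not tested, except that some fits hold more libraries or genes.

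Training calls, 0 by edgeR in each class, became with DESeq2 5 in DAL, 5 in gamma, 32 in V2, 3 in V3, 20 in 3-86 and 37 in R27G01, and 15 for the difference between Kenyon cell classes. In simulated counts most DESeq2 calls in 3-86 and R27G01 were of unchanged genes. One fit of all 14 groups gave 2 in DAL, 96 in 3-86 and 427 in R27G01. Without a filter on low counts there were 2 calls in alpha/beta, 1 in V2 and 2 in R27G01, and voom gave 2 in V2. The other alternatives for training gave 0, except a block in gamma described below. Genes whose training effect differed between classes numbered 122, and 403 with DESeq2 (78 shared), 9 with voom and 275 without the mixed libraries.

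With the whole flies of each driver subtracted, the counts were 1721 for Kenyon cells against other neurons (main 2912), 5 for alpha/beta against gamma (2), 61 for DAL (983), 546 for gamma (1509), 802 for alpha/beta (1736), 5 for V2 (392), 3 for V3 (532), 863 for 3-86 (1934) and 904 for R27G01 (1552). Adding trained libraries with training as an additive term gave 61 for alpha/beta against gamma, 2484 for gamma, 2632 for alpha/beta, 1035 for V2, 960 for V3, 2971 for 3-86 and 2701 for R27G01. Without a filter there were 2503 for gamma, 3173 for alpha/beta, 757 for V2 and 1039 for V3. Alpha/beta against gamma gave 73 with DESeq2 and 118 in a fit of their own, and V2 gave 857 with DESeq2. Whole-fly genotypes differed in 2998 genes, 4663 with DESeq2, 1713 with NP1131 and G386 flies summed by description number and 1364 over the 7 drivers. For c739 against NP1131 flies 501 became 1061 with DESeq2, 313 without a filter and 65 with those sums.

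Leaving out each library in turn gave 616 counts, of which 597 lay within 1.5 times the main count. Ranges were 0 to 4 for training in gamma (4 without gamma control library 2), 0 to 0 for training in the other classes and between Kenyon cell classes, and 42 to 228 for the class-by-training genes. For the latter, 8 libraries moved the count: R27G01 trained 1 (45) and 2 (42), gamma control 4 (64) and 5 (80), 3-86 trained 2 (228) and 4 (74), 3-86 control 3 (187) and alpha/beta control 6 (78). Kenyon cells against other neurons ranged from 2674 to 3152, alpha/beta against gamma from 2 to 2, gamma from 1138 to 1682, alpha/beta from 1404 to 1926, 3-86 from 1539 to 2247 and R27G01 from 1042 to 1625. DAL ranged from 620 (without DAL control 4) to 1233, V2 from 221 (V2 control 3; 256 without V2 control 1) to 532, and V3 from 298 (V3 control 4) to 721. Neurons against whole flies ranged from 6590 to 6895 and genotypes from 2282 to 3612. For c739 against NP1131 flies the range was 133 (c739 1) to 1086 (c739 2), with 774 without DAL-GAL4 3 and 208, 184 and 246 without NP1131 1, 3 and 4.

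For 100 named genes in a comparison, 3754 of 3843 values kept direction and side of the threshold, 55 no longer passed, 31 newly passed and 3 reversed. The reversed ones were elav in 3-86 (log2 fold change 0.28 with whole flies subtracted), Pdf in V3 (-0.84 without V3 control 1; highest 9.70, without V2 control 2) and Hsp70Aa in gamma (-1.70 without gamma control 3; highest 4.01, without alpha/beta control 6); for the last pair 1 library carried the level. With whole flies subtracted, 31 of 61 values no longer passed, among them Vmat, Tbh and Tdc2 in V3 (8.09, 7.62 and 8.89). Since those log2 fold changes stayed large, a lost call there does not by itself show that genetic background accounts for a difference.

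The letters in the deposited sheet are not explained there and were not taken to pair the libraries. In V3, where each of 5 letters joins a control and a trained library, their deviations correlated at 0.00828 to 0.176, over 0.1 for 3 of 5, and averaged 0.0943 against -0.022 for other pairs. With the letter as a replicate block training gave 0 calls in each class where it could be fitted. The first 2 digits of the title codes as a block gave 0 too, and the full code as a block gave 1 call in gamma, where those digits are shared. Neither 3-86 nor R27G01 has more than 1 letter, so those fits could not be made. A limma fit of the deposited corrected CPM was not run, since its columns could not all be matched to libraries.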

Other observations

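The test of Hr38 in both Kenyon cell classes was chosen only after its value in alpha/beta cells was seen. Hr38, an activity-regulated nuclear receptor gene, had 1390 CPM in trained and 755 in control alpha/beta libraries, and 2080 and 1320 in gamma. It lay above the control mean in 5 of 6 and 6 of 6 trained libraries. An exact permutation test within class over both classes gave p = 0.000883, and 0.00971 after adjustment over 11 activity-regulated genes. CG17778 had p = 0.007 in the same test, adjusted to 0.0385, and the other 9 genes did not pass. That activity-regulated genes as a list are higher in trained Kenyon cells stays open, since 2 of 11 passed. The mean log2 differences of kay and CG14024 were negative, -0.143 and -0.311, without passing. For kay the mean in alpha/beta libraries was higher after training, 39.7 against 34.9 CPM. Adjusted over all genes Hr38 did not pass (edgeR adjusted p = 0.994 in the fit of both classes), and the test rests on the same libraries in which the gene was noticed.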
